A study of Mus musculus with 2 samples.

How the data were processed

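Trimethylation of lysine 4 of histone H3 (H3K4me3), a chromatin mark found mainly at the promoters of active or poised genes, was profiled by chromatin immunoprecipitation and sequencing in the hindbrain of mouse embryos at embryonic day 12.5. The 2 libraries were biological replicates per the labels: replicate 1 came from a pool of 120 embryos and replicate 2 from a separate pool of 88 embryos of the strain B6NCrl, both sexes mixed. They form 1 group, so no comparison between conditions was possible, and the design implied a description of the tissue's H3K4me3 landscape and of the agreement of the replicates.

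The values analysed were 4 peak lists in narrowPeak format. Per the text files that accompany the lists, 1 list was called on the filtered alignments of each replicate against a control, another was called on the alignments of both replicates together against both controls (the pooled list), and the last held the replicated peaks derived from the other lists. A check of the intervals found that all 23528 replicated peaks were intervals of the pooled list with the same fold. The build was mm10 (GRCm38) per the labels. The aligner, the peak caller, its threshold and the rule for calling a peak replicated were not given in the sources used here. Each peak carried a fold enrichment over control, a ratio computed by the authors, and a −log10 p-value and −log10 q-value, also deposited by the authors. The lowest −log10 p in the replicates' lists was 2.00 in replicate 1 and 2.06 in replicate 2. These values are each peak's own and were used only to describe, rank or filter peaks. Peak lists hold no read counts, so the depth of each library is unknown, and no counting interval or detection floor could be given. A promoter without a peak is therefore a promoter below the authors' threshold, not one shown to lack the mark. The control alignments were not used here.

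Peaks were set against the GENCODE mouse annotation, release 21 of the M series, on the same build. A promoter was defined as 1000 bp either side of any annotated transcript start of a protein-coding gene, and a gene was called marked when a replicated peak overlapped its promoter by at least 1 bp. Genes were counted by annotation identifier, and 36 of the 22028 repeat the symbol of another. Each peak was assigned to the first of these classes that it touched: protein-coding promoter, promoter of another gene, exon, intron, intergenic. Peaks separated by gaps of up to 1000 bp were merged into domains, and the breadth of a marked gene was the length of the widest domain touching its promoter. The height of a promoter was the highest fold enrichment of a replicate's own peaks touching it, given as mean ± SD over the 2 replicates. A replicate without a peak there entered that mean as 0. Overlaps were computed with numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15 and checked against bedtools 2.31.1. Plots were drawn with matplotlib 3.10.9.

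For each of 18 lists of genes the share of marked members was compared with that of all other protein-coding genes by a two-sided Fisher's exact test (scipy 1.17.1), with Benjamini-Hochberg adjustment over the 18 lists. The genes are the units of these tests, not replicates, so their p-values describe 1 peak list and not the variation between embryos. Each replicate's own list was therefore used to repeat every call. The median breadth of a list's marked members was placed by percentile among 10000 random lists of as many marked genes, as a description and not a test. Percentiles are given for the 16 lists with at least 3 marked members. For Hox genes the percentage of the bases within 2000 bp of a gene's own starts covered by peaks was compared between paralog groups 1 to 4 and 10 to 13 by a two-sided permutation test with 100000 resamples. Differences between the replicates were described by the log2 ratio of height, replicate 2 over replicate 1, centred on its median, because 1 library on each side allows no test.

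The 18 lists, the tests and all settings above were fixed before the data were examined, and so was the rule for the genes named. That rule took, per list, the 2 to 4 marked members with the greatest breadth and up to 4 unmarked members in list order, then the 20 widest promoter domains, the 5 genes per direction that differed most between the replicates, and the 10 widest domains touching no annotated promoter. The alternatives tried were each replicate's list alone, peaks with a −log10 q of at least 5, the 20000 peaks per list with the highest −log10 p, promoters of 500 bp or 2500 bp either side, and at least 50% of the peak inside the promoter or the other list. For breadth they also included no merging, merging over gaps of up to 3000 bp and random lists matched on height. The Hox comparison was repeated with 5000 bp either side. Starts of protein-coding transcripts alone were added as an alternative after the data were seen. On simulated marks for 22028 genes, the Fisher test called 100% of 100 lists of 20 genes with a planted share of 99% or 20% marked and 0% of the lists with no effect. The breadth percentile lay above 95 for 100% of lists with doubled breadth and for 8% of lists with none.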

Results

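H3K4me3 was mapped in the hindbrain of mouse embryos at embryonic day 12.5, when the tissue holds dividing neural progenitors and newly formed neurons. The group comprised 2 biological replicates, of 120 and 88 pooled embryos. The authors called 29507 peaks in replicate 1 and 28130 in replicate 2, and their list of replicated peaks held 23528 peaks covering 37.8 Mb. All coordinates refer to mm10.

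Protein-coding promoters carried most of the mark. Of the replicated peaks, 65.6% touched such a promoter, and these peaks held 83.1% of the total peak width. In the replicates' own lists the share was 58.9% ± 2.11 (SD, n = 2). A further 5.57% of the replicated peaks touched promoters of other genes, 5.47% lay in exons, 10.6% in introns and 12.7% between genes. Promoter peaks had a median fold enrichment of 37.0, against 3.88 for intronic and 5.37 for intergenic peaks. In total 14515 of 22028 protein-coding genes (65.9%) were marked, and the replicates' own lists marked 14573 ± 50.9 (SD, n = 2). Both replicates marked 14452 genes, replicate 1 alone marked 157 and replicate 2 alone marked 85.

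The replicates shared their strong peaks and differed in their weak ones. Of the peaks of replicate 1, 78.6% touched a peak of replicate 2, and 86.9% of the peaks of replicate 2 touched one of replicate 1, with a base-pair Jaccard index of 0.812. Among the peaks in the lowest quartile of fold enrichment these shares were 31.8% and 53.8%, and in each of the upper 2 quartiles they were 100% in both directions. Of the replicated peaks, 92.8% touched a peak in each replicate's own list. The others had a median fold enrichment of 3.14, against 25.3 for the peaks present in both.

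Hox genes, whose clusters give cells their position along the head-to-tail axis, were examined by paralog group. All 12 genes of groups 1 to 4, which include those expressed in the rhombomeres, were marked (adjusted p = 0.0169, Fisher's exact test). Their median breadth of 14380 bp lay at percentile 100 of random lists. It was 4832.5 bp when no gap was merged. Hoxb3 and Hoxb4 shared a domain of 49704 bp with Hoxb5 and Hoxb6 (chromosome 11, 96297148 to 96346851), with a height of 23.0 ± 1.49 (SD, n = 2) at Hoxb3. Hoxa1 and Hoxa2 shared 24773 bp (chromosome 6, 52156532 to 52181304), with a height of 37.6 ± 4.23 (SD, n = 2) at Hoxa2. In groups 5 to 9, which pattern the trunk, 14 of 15 genes were marked (adjusted p = 0.0373, Fisher's exact test), with a median breadth of 3390 bp at percentile 99.9. Hoxa5 and Hoxa6 lay in 12657 bp, and Hoxc9 had no replicated peak. In groups 10 to 13, which pattern the caudal body, 9 of 12 genes were marked and the share did not differ from that of other genes (adjusted p = 0.762, Fisher's exact test). The share lay below that of other genes in replicate 2's own list (7 of 12, 58.3% against 66.0%; adjusted p = 0.589, Fisher's exact test) and with −log10 q of at least 5 (6 of 12, 50% against 65.6%; adjusted p = 0.433, Fisher's exact test). Their median breadth was 503 bp, at percentile 0, but 744 and 853 bp in the replicates' own lists, 766 bp with promoters of 500 bp and 1039.5 bp with −log10 q of at least 5. The widest of these domains were 1633 bp at Hoxc13, 1456 bp at Hoxa13 and 1226 bp at Hoxd11, and Hoxc11, Hoxc12 and Hoxd12 were unmarked.

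Peaks covered 70.1% ± 27.4 (SD over 12 genes) of the bases around the starts of groups 1 to 4, 41.8% ± 29.8 (SD over 15 genes) in groups 5 to 9 and 13.1% ± 11.6 (SD over 12 genes) in groups 10 to 13. Groups 1 to 4 exceeded groups 10 to 13 by 56.9 percentage points (permutation test, p = 4e-05). In the replicates' own lists the means were 67.7% ± 2.56 for groups 1 to 4 and 10.8% ± 0.716 for groups 10 to 13 (SD, n = 2). Neighbouring Hox genes are not independent: the 12 genes of groups 1 to 4 lay in 9 domains and the 14 marked genes of groups 5 to 9 in 11. The permutation p and the percentiles therefore overstate the number of separate observations. In groups 5 to 9 the domains of 49704, 12657 and 5436 bp each counted for a pair of genes. Of their other domains, those of 3810 and 2970 bp exceeded the 2157 bp of all marked genes. The rest measured 1450 bp or less. When at least 50% of a peak had to lie inside the promoter, 6 of 12 genes of groups 1 to 4 (50%) and 10 of 15 of groups 5 to 9 (66.7%) were marked and neither call held (adjusted p = 0.668 and 1, Fisher's exact test). In groups 10 to 13, 9 of 12 (75.0%) were still marked, so the order of the marked shares turned round.

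**Figure D1:**
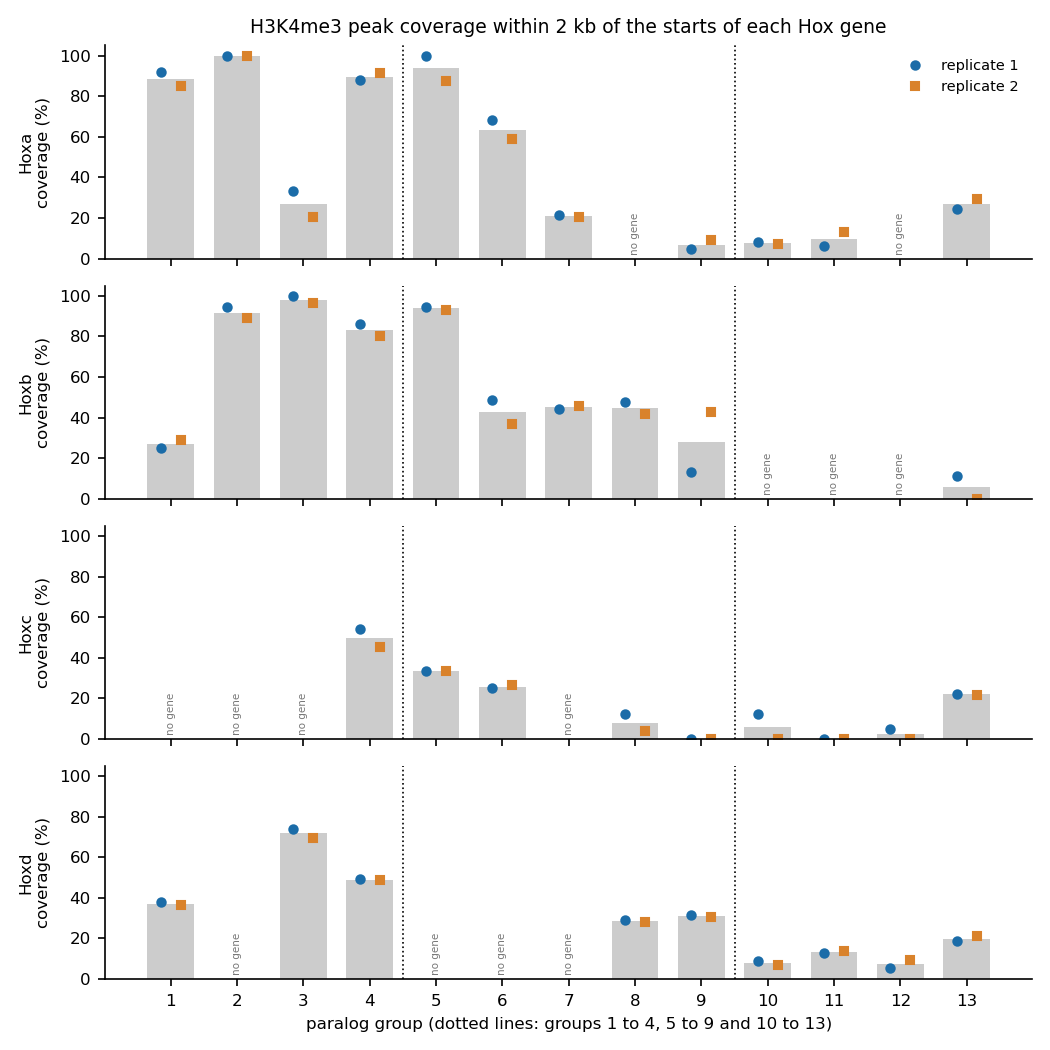
Percentage of the bases within 2000 bp of each Hox gene's starts that is covered by H3K4me3 peaks (vertical axes), by paralog group (horizontal axis) in the 4 Hox clusters. Points are the 2 replicates, bars their mean, and "no gene" marks positions without a gene in that cluster. Coverage averaged 67.7% in groups 1 to 4 and 10.8% in groups 10 to 13 over the replicates.

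Regulators of hindbrain and isthmus patterning were all marked, in wide domains: 25 of 25 genes (adjusted p = 0.000233, Fisher's exact test), with a median breadth of 6343 bp at percentile 100. Pax3, a dorsal neural tube regulator, lay in 17212 bp (10837 bp in replicate 2's own list) with a height of 21.8 ± 4.42, Meis1, a Hox cofactor, in 14515 bp with 40.1 ± 0.0903, and En1, which is expressed at the isthmus, in 13902 bp with 22.4 ± 5.36 (SD, n = 2). Irx2 lay in 13011 bp. Regulators of the forebrain and other anterior regions were also all marked, 25 of 25 (adjusted p = 0.000233, Fisher's exact test). Their median breadth was 3069 bp and their median height 10.2 ± 0.121, against 17.5 ± 0.312 for the hindbrain list (SD, n = 2). The widest were Otx1 with 9333 bp, Lhx2 with 8290 bp, Dlx2 with 6544 bp and Emx2 with 5580 bp, the last 2 with 4154 and 2624 bp in replicate 2's own list.

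The position of the forebrain list among random lists depended on the merging of peaks. It was percentile 99.8 with gaps of up to 1000 bp merged and 3.11, with a median of 1686 bp, when no gap was merged, and replicate 2's own list gave 93.9. The hindbrain list stayed at percentile 100 in each of these cases, but its call of marked genes ended when 50% of a peak had to lie inside the promoter (16 of 25 genes, 64.0%; adjusted p = 1, Fisher's exact test).

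Genes of neural progenitors and of differentiating neurons were marked without exception in the lists examined. All 20 progenitor genes were marked (adjusted p = 0.00103, Fisher's exact test), with a median breadth of 6733 bp at percentile 100. Sox2, a factor that maintains progenitors, lay in 17747 bp (10239 bp in replicate 2's own list) with a height of 35.6 ± 0.872, and Pax6 in 16445 bp with 25.0 ± 0.664 (SD, n = 2). Msi1, an RNA-binding protein of progenitors, lay in 11901 bp and Sox11 in 9682 bp. All 20 neuronal genes were marked as well (adjusted p = 0.00103, Fisher's exact test), with a median breadth of 4525 bp at percentile 100. Among these were Myt1l with 12907 bp, Tubb3, a neuronal tubulin, with 7878 bp, Nefm with 7595 bp and Elavl4 with 7406 bp. With 50% of a peak required inside the promoter, the progenitor list was 50% and the neuronal list 55.0% marked, below the 62.7% of other genes, and neither differed from them (adjusted p = 0.508 and 0.741, Fisher's exact test).

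Genes that set neurotransmitter identity were marked in 11 of 14 cases, a share that did not differ from other genes (adjusted p = 0.465, Fisher's exact test). The marked members had a median breadth of 5363 bp at percentile 100, and 3423 bp with −log10 q of at least 5. The widest were the inhibitory transporter gene Slc32a1 with 12461 bp and a height of 22.1 ± 1.39, the GABA-synthesis gene Gad1 with 11070 bp and 19.3 ± 0.427, and the glutamate transporter gene Slc17a6 with 10562 bp and 12.5 ± 2.52 (SD, n = 2). The glycine transporter gene Slc6a5 lay in 9091 bp. Chat and Slc18a3, also named outside the rule, share 1 domain of 5363 bp, the median, which is counted for both genes. The monoamine-synthesis genes Tph2, Th and Dbh were unmarked. The monoamine-neuron genes Slc6a4 and Fev of the same list, named here outside the rule, were marked in 1985 and 1747 bp (Fev in 4186 bp in replicate 1's own list).

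The glial, endothelial and mesenchymal lists did not pass the test. In the glial list 8 of 15 genes were marked (adjusted p = 0.465, Fisher's exact test). They included Olig2, an oligodendrocyte lineage regulator, with 6085 bp (2313 bp in replicate 2's own list), Sox10 with 3618 bp (5552 bp in replicate 1's) and Slc1a3, a glutamate transporter of radial glia, with 3147 bp. Of the genes of mature glia, Gfap, Aqp4, Plp1 and Mog were unmarked, while Mbp and Cnp, named here outside the rule, were marked in 2123 and 1157 bp. The Mbp domain (chromosome 18, 82474697 to 82476819) spanned the first annotated start of a gene that runs to 82585637. Which Mbp transcript it belongs to was not examined. The median breadth was 1889.5 bp at percentile 23.1, and at 86.7 among random lists matched on height. In the endothelial list 8 of 14 were marked (10 of 14 in replicate 1's own list; adjusted p = 0.608 and 0.785, Fisher's exact test), with Sox17 at 2284 bp and Kdr at 2175 bp (3480 bp in replicate 2's own list), Pecam1, Cdh5, Tek and Tie1 unmarked, and a median of 1972 bp at percentile 30.2, or 85.6 when matched on height. In the mesenchymal and meningeal list 12 of 14 were marked (adjusted p = 0.206, Fisher's exact test), with a median breadth of 4244 bp at percentile 99.99. Pdgfra lay in 8940 bp with a height of 24.9 ± 2.03 and Foxc1, a regulator of meningeal development, in 8170 bp with 19.2 ± 3.24 (SD, n = 2). Lum and Dcn were unmarked. In the list of replicate 1 alone the median was 2672 bp, at percentile 91.8.

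Blood and myeloid genes were marked less often than other genes. In the erythroid list 4 of 15 were marked (adjusted p = 0.00364, Fisher's exact test): Epor with 2051 bp, Klf1 with 1536 bp, Gypa with 985 bp and Slc4a1 with 278 bp. The globin genes Hbb-bt, Hbb-bs, Hbb-y and Hbb-bh1 were unmarked. The median breadth of the 4 genes, 1260.5 bp, lay at percentile 2.17, and at 38.2 among random lists matched on height. None of the 14 microglia and macrophage genes was marked (adjusted p = 5.15e-06, Fisher's exact test), Csf1r and Cx3cr1 among them. Replicate 2's own list had peaks at 2 of them, Spi1 and Aif1, and replicate 1's at 0.

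Lists chosen for lineages outside the tissue were also marked less often. Whether any of their members is also used by cells of the hindbrain was not examined. In the liver list 1 of 15 genes was marked (adjusted p = 2.63e-05, Fisher's exact test), Foxa3, with a height of 52.0 ± 2.82 (SD, n = 2), while Alb, Afp, Ttr and Apoa1 were not. The peak at Foxa3 lay upstream of the gene and also touched the promoter of Sympk. In the striated muscle and heart list 4 of 15 were marked (adjusted p = 0.00364, Fisher's exact test): Myod1 with 2507 bp, Ckm with 1856 bp, Gata4 with 1101 bp and Nkx2-5 with 509 bp. The peak at Ckm also touched the promoter of Klc3. In replicate 1's own list Ckm lay in 961 bp and Gata4 in 515 bp. With promoters of 2500 bp either side this call ended, at 6 of 15 genes (adjusted p = 0.0689, Fisher's exact test). Their median breadth lay at percentile 6.27, between 0.17 and 4.15 under 6 of the alternatives, at 65.7 with gaps of up to 3000 bp merged and at 72.2 when matched on height. In the germline and pluripotency list 3 of 15 were marked (adjusted p = 0.00103, Fisher's exact test), Dazl, Tdrd1 and Dppa3, in domains of 833, 452 (203 in replicate 2's own list) and 301 bp, with a median at percentile 0.09, and Pou5f1 and Nanog were not.

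Genes used by every cell were marked throughout and had the highest median heights among the 16 lists with at least 3 marked genes. All 18 housekeeping genes were marked (adjusted p = 0.00147, Fisher's exact test), with a median breadth of 3386 bp at percentile 99.95 and a median height of 48.6 ± 3.69 (SD, n = 2). Eef2 lay in 6093 bp and Actb in 5626 bp. All 20 chromatin regulators were marked (adjusted p = 0.00103, Fisher's exact test), with a median breadth of 3136 bp at percentile 99.8 and a median height of 48.3 ± 2.39 (SD, n = 2). Among these were Setd1b, a subunit of a complex that deposits H3K4 methylation, with 12065 bp, and Ring1, a Polycomb protein, with 10477 bp. Most of each of these 2 domains lay upstream of the gene. That of Ring1 ran to 34034078, past the gene's end at 34024680, and that of Setd1b began at 123133789, before the gene's start at 123142193. Whether they span promoters of neighbouring genes was not examined. Their call ended when 50% of a peak had to lie inside the promoter (14 of 20 genes; adjusted p = 0.774, Fisher's exact test). Over all lists, 8 were marked more often than other genes, 5 less often and 5 did not pass the test.

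**Figure D2:**
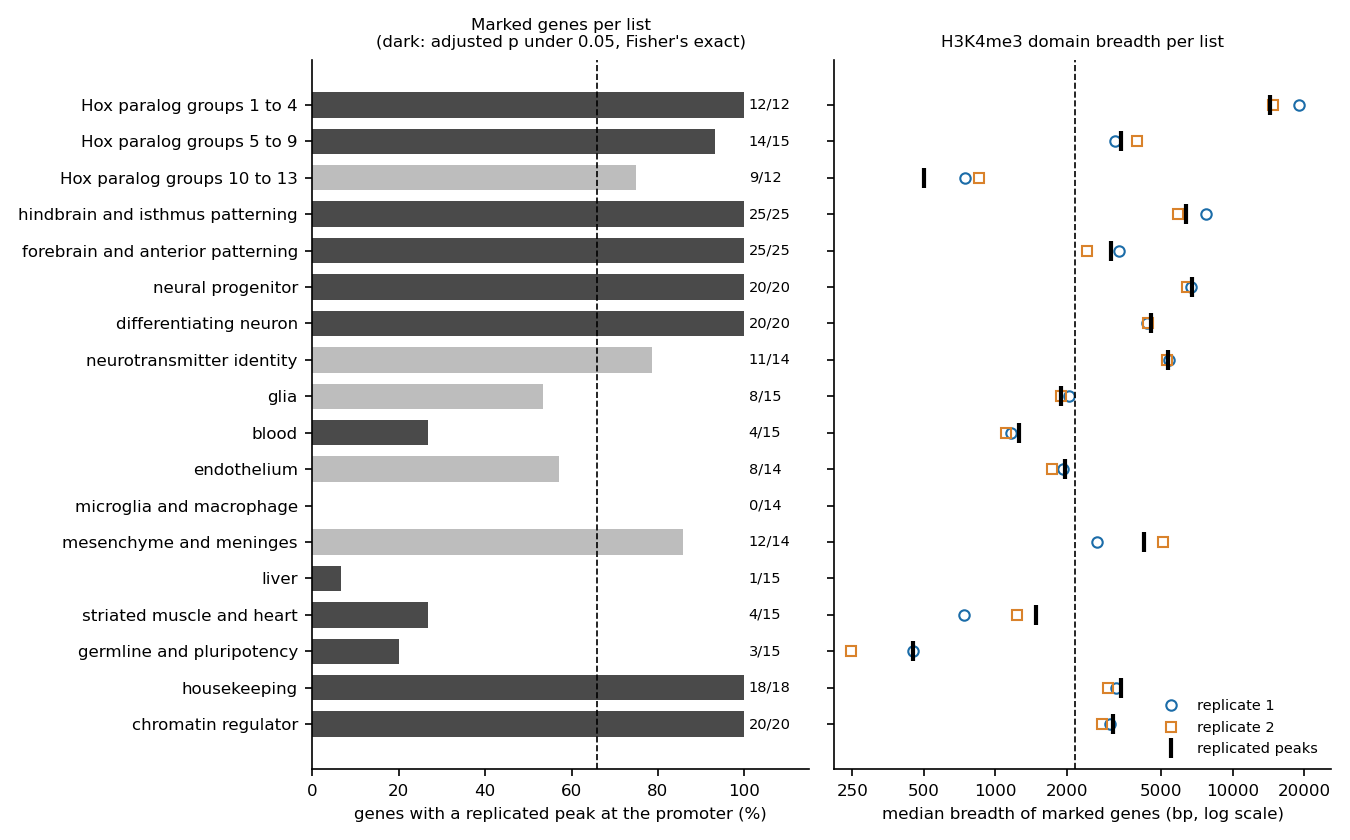
Left, percentage of the genes of each fixed list with a replicated H3K4me3 peak at the promoter (horizontal axis), with the counts, dark bars for lists that passed the test (microglia and macrophage, at 0 of 14, also passed) and a dashed line at the share of other genes. Right, median domain breadth in bp on a log axis, with circles and squares for the replicates' own lists, a black mark for the replicated peaks, a dashed line at the 2157 bp of all marked genes and no points for lists with fewer than 3 marked genes. Hox groups 1 to 4 lay at 14380 bp and Hox groups 10 to 13 at 503 bp (744 and 853 bp in the replicates' own lists).

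The widest H3K4me3 domains depended on the merging of peaks and, for 4 of the 20, on the replicate. The median breadth of all marked genes was 2157 bp, and 95 genes (0.654%) lay in domains of over 10 kb. The widest was the domain of Hoxb3 to Hoxb6 given above. Next came Pou3f3, a POU factor of neural cells, with 30788 bp (chromosome 1, 42683946 to 42714733; height 58.5 ± 3.21), and Nr2f2, a nuclear receptor, with 24999 bp (chromosome 7, 70345789 to 70370787; 52.0 ± 6.13; SD, n = 2). The Hox cofactor gene Meis2 lay in 24416 bp (chromosome 2, 116052088 to 116076503), Ebf3, a factor of early neurons, in 20042 bp (chromosome 7, 137303327 to 137323368) and Lhx1, in a domain shared with Aatf, in 19311 bp (chromosome 11, 84512593 to 84531903). Gata3 followed with 19197 bp but 9300 and 7975 bp in the replicates' own lists, the domain of Hoxd3 and Hoxd4 with 18680 bp, and Lhx5 with 16927 bp. The remaining domains of the 20 widest lay at Hoxa1 and Hoxa2, Sox2, Pax3, Pax6, Bahcc1, Tbx2, Mn1, Pou3f2, Nr2f1, Irx5 and Meis1, the last with 14515 bp. When no gap was merged, 14 of the 20 breadths changed by more than 1.5-fold: that of Hoxb6 fell to 11579 bp, of Pou3f3 to 18840 bp, of Nr2f2 to 8682 bp, of Ebf3 to 12151 bp and of Sox2 to 4203 bp. In replicate 2's own list 4 did so, at Gata3, Sox2, Pax3 and Aatf, whose widest domain fell to 1818 bp while that of Lhx1 stayed at 15924 bp. The peaks of each replicate covered most of every one of these domains, from 69.6% at Pax6 in replicate 2 to 99.5% at Lhx5 in replicate 1.

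Wide domains that touched no annotated promoter were shorter. The widest measured 8669 bp and lay between genes (chromosome 2, 115852495 to 115861163). Its nearest protein-coding start, 7.70 kb away, was a start of Meis2, but not one within the wide Meis2 domain given above (116052088 to 116076503). The next lay 2.49 kb from a start of Pax2 and measured 7214 bp (chromosome 19, 44746340 to 44753553). The promoter domain of Pax2 began at 44754792, just past the merging gap of 1000 bp. Others lay 5.81 kb from Trim27 with 6898 bp, 21.6 kb from Hfe2 with 6842 bp, in an intron of the non-coding gene Lncppara with 6299 bp, 12.2 kb from Cbx8 with 6086 bp and in an intron of Bcor, a corepressor gene, with 5620 bp. The last of the 10 were near Aen, near Msx2 and in an intron of Bcl6. Their highest fold enrichments in the pooled list ranged from 6.87 near Meis2 to 42.6 in Lncppara.

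Promoter heights were close in the replicates for most genes. Over the 14452 genes marked in both, the log2 ratio of replicate 2 over replicate 1 had a median of 0.06 and an SD of 0.34, and heights correlated across genes with Pearson's r = 0.928 on the log2 scale and Spearman's rho = 0.838. Genes are not independent replicates, and no p is given. After centring, 121 genes (0.837%) differed by more than 2-fold, 61 of them lower in replicate 2 and 60 higher. The largest ratios toward replicate 1 were those of Adhfe1 (43.4 in replicate 1 and 6.43 in replicate 2), Tmem102 (26.3 and 5.46), Mvp (28.2 and 6.25), Apobr (13.96 and 3.80) and Ehbp1l1 (47.4 and 13.5). The largest toward replicate 2 were those of P4hb (17.6 and 52.0), 6430628N08Rik (4.25 and 11.7), Col4a6 (5.43 and 14.6), Dnah8 (2.21 and 5.84) and Zfp940 (10.4 and 27.4). With breadth in place of height, 262 genes differed by more than 2-fold. With 1 library on each side, none of these differences could be tested.

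**Figure D3:**
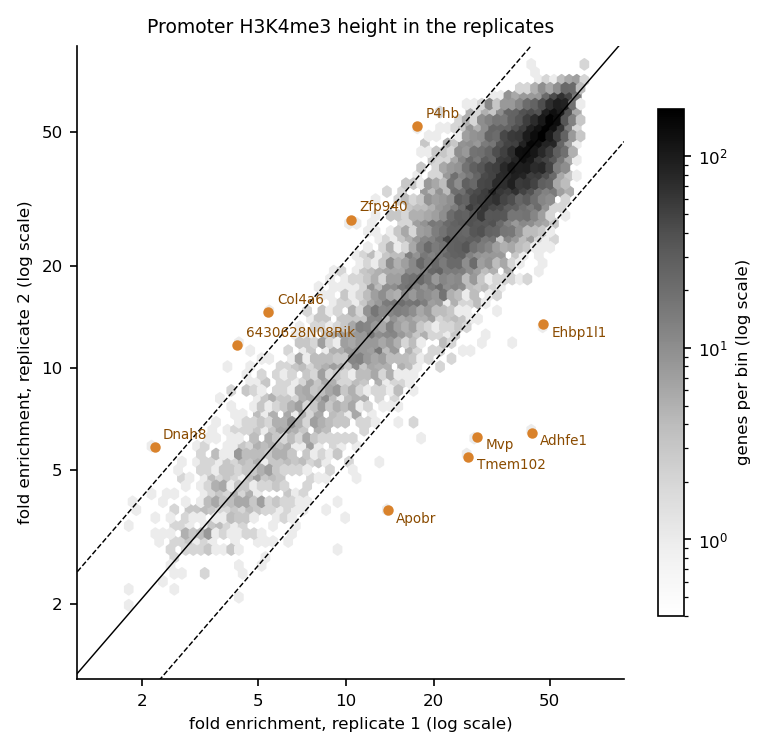
Highest fold enrichment at each promoter in replicate 1 (horizontal axis, log scale) and replicate 2 (vertical axis, log scale) for the 14452 genes marked in both, shaded by the number of genes per bin on a log scale. The solid line is the median ratio, the dashed lines lie 2-fold away from it, and orange points are the 10 named genes. Outside the dashed lines lay 121 genes.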

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

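The starts of protein-coding transcripts alone were the 1 alternative chosen after the results were seen. The replicate overlap rose when weak peaks were removed: with −log10 q of at least 5 it was 91.6% of the peaks of replicate 1, 96.8% of those of replicate 2 and a Jaccard index of 0.854, and with the 20000 strongest peaks 93.6%, 95.9% and 0.857. When at least 50% of a peak had to be covered by the other list, it fell to 73.8% of the peaks of replicate 1 and 83.3% of those of replicate 2. With 1 replicate left out, all peaks of the other's own list were used, without the authors' filter for replication, and the promoter share was 57.4% to 60.4%. Among replicated peaks it was 69.3% with −log10 q of at least 5, 63.2% and 72.6% with promoters of 500 and 2500 bp, 61.3% with 50% of the peak inside the promoter and 62.6% with protein-coding transcript starts.

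Of 126 list calls recomputed, 116 kept their direction and side of the threshold. Among the lists that did not pass the test, Hox groups 10 to 13 ranged from 58.3% to 75.0% marked and endothelium from 64.3% to 71.4% when 1 replicate was left out, and Hox groups 10 to 13 were at 50% with −log10 q of at least 5. These 3 changes of direction involved 2 lists, and the cause was not tested. The striated muscle list lost its call with promoters of 2500 bp, at 40.0% marked. The other 6 changes came from requiring 50% of the peak inside the promoter, under which 2 lists (forebrain and housekeeping) were marked more often: Hox groups 1 to 4 reversed to 50%, progenitors to 50% and neurons to 55.0%, and Hox groups 5 to 9 (66.7%), hindbrain (64.0%) and chromatin regulators (70.0%) lost the call. This follows from the construction, since a peak much wider than the promoter cannot have 50% of its length inside it. The Hox coverage difference ranged from 54.1 to 58.9 percentage points over its 4 alternatives. Of 143 breadth percentiles recomputed, 132 kept their side of the 5th and 95th percentiles. Without merging, 5 lists lay below the 5th, and the forebrain list reversed to 3.11. For the forebrain list the cause was not tested. Of 160 breadths recomputed for the 20 widest domains, 118 stayed within the SD of the replicates. With breadth in place of height, 262 genes differed by more than 2-fold between the replicates, and the cause was not tested. Depth is unknown, and why weak peaks of 1 replicate were often absent from the other was not tested.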

Other observations

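The gene families below, taken by symbol, and the tests of chance assignment, of blood cells and of the genes whose summits lay outside their promoters were chosen after the results were seen. Families of sensory and epithelial genes were marked less often than other genes: 3 of 1135 olfactory receptor genes, 1 of 331 vomeronasal receptor genes, 8 of 53 keratin genes (adjusted p = 1.1e-13, Fisher's exact test over 18 families) and 0 of 42 beta-defensin genes (adjusted p = 1.33e-19, Fisher's exact test) were marked. The clustered protocadherins, a family of adhesion molecules, were marked in 24 of 57 cases, less often than other genes (adjusted p = 0.00081, Fisher's exact test), with a median breadth of 771.5 bp at percentile 0. The widest were Pcdhgc3 with 4697 bp, Pcdhgc4 with 3196 bp, Pcdhga12 with 2539 bp and Pcdhga11 with 2424 bp, each above the 2157 bp of all marked genes. By cluster, 3 of 14 alpha, 2 of 22 beta and 19 of 21 gamma genes were marked, and the clusters were not tested against one another. The alpha genes include 2 annotated genes with the symbol Pcdha11, both unmarked, so 13 symbols stand for 14 genes. In the replicates' own lists 27 and 25 of the 57 clustered protocadherins were marked. How uniquely reads map to their similar copies was not examined. All 73 cytosolic ribosomal protein genes and all 78 mitochondrial ones were marked, with median breadths of 2645 and 1839 bp, at percentiles 99.9 and 0.53.

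Of the families of developmental transcription factors, 3 were marked more often than other genes. SOX factors were marked in 18 of 19 cases (adjusted p = 0.0113, Fisher's exact test) with a median breadth of 4857.5 bp, FOX factors in 38 of 44 (adjusted p = 0.00729, Fisher's exact test) with 2828 bp and LIM homeobox factors in 12 of 12 (adjusted p = 0.0185, Fisher's exact test) with 7013.5 bp. The small ZIC and Iroquois families had 5 of 5 and 6 of 6 marked (adjusted p = 0.202 and 0.147, Fisher's exact test). Every member was marked, so families of this size could not pass as marked more often. They had the greatest median breadths of the 18 families, 13492 and 9276 bp, at percentile 100. Zic1 and Zic4 share 1 domain. T-box factors, marked in 13 of 15 cases, had a median of 1727 bp at percentile 7.52, between the 5th and 95th percentiles. Their breadths were mixed. Tbx2 with 15959 bp, Tbx1 with 11014 bp, Tbx3 with 4760 bp, Tbx15 with 4253 bp and Eomes with 3380 bp lay above the 2157 bp of all marked genes. The other marked T-box genes lay below it.

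Hindbrain patterning genes lay in wider domains than forebrain patterning genes, although all genes of both lists were marked. The mean log2 breadth differed by 1.24, a ratio of 2.37 (permutation test, p = 4e-05), by 1.15 in replicate 1 and 1.76 in replicate 2, and by 1.21 with no gap merged. The contrast was not among the comparisons fixed beforehand and was tested on the same genes and peak list. Its permutation p therefore cannot exclude chance in the choice of the contrast. The difference was 1.23 after adjustment for CpG number within 5000 bp and 1.28 after adjustment for the extent of annotated starts. CpG number and the extent of starts are thus each argued against as its whole cause. CpG density was not examined. Height differed too, 1.83-fold (permutation test, p = 0.00038), and adjustment for it left 0.78 (permutation test, p = 0.00098), so part of the difference in breadth goes with height. Expression was not analysed here, and no biological explanation was tested.

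The blood, liver, muscle and germline lists held 12 marked genes between them. The liver, muscle and germline lists were chosen for lineages outside the tissue, whereas the blood list was chosen for cells that the dissected tissue could hold. In 2 of the 12 (16.7%) the peak also touched another protein-coding promoter, against 21.8% of other marked genes (p = 1, Fisher's exact test). A peak of a neighbouring protein-coding gene is argued against for the rest, whose peaks touched no other such promoter. The 2 were Foxa3 with Sympk and Ckm with Klc3, for which it stays open. Their domains lay outside the gene, which goes with a neighbour's peak. That of Foxa3 was at 19023802 to 19025473, past the gene's end at 19023538. That of Ckm was at 19402601 to 19404456, before the gene's start at 19404776. Blood cells as the source of the peaks at Klf1, Epor, Gypa and Slc4a1 stay open. Of the 11 unmarked erythroid genes 1, Ermap, had a peak in the pooled list, but these genes were selected for lacking a replicated peak, so that count decides nothing. What marks these promoters stays open, and no biological explanation was tested.

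Of the 121 promoters whose height differed more than 2-fold between the replicates, most were not explained by a peak joined to a stronger neighbour. In 9 of them (7.44%) the tallest peak had its summit outside the promoter in at least 1 replicate, against 3.27% of other genes (p = 0.019, Fisher's exact test), so this artifact may account for those 9 but not for the other 112. The 9 include 6 of the 10 named genes, whose breadths in replicates 1 and 2 were 3535 and 3546 bp (Adhfe1), 5990 and 6248 (Tmem102), 3377 and 3378 (Mvp), 7821 and 7093 (Ehbp1l1), 2605 and 2589 (Col4a6), but 1487 and 193 (Apobr). Counting noise at weaker peaks is a candidate explanation for part of the 121: the higher of the 2 folds lay under the median of all genes in 59.5% of them and in 58.0% of the 112, with a median over the 121 of 35.7 against 40.0 for other genes. That excess is small, and 1 library on each side leaves a difference between the pools of embryos open and untested.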
